A study of Capra aegagrus with 10 samples.

How the data were processed

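The small RNA content of 10 libraries from mammary gland cells of a dairy goat was measured by sequencing, with 2 libraries in each of 5 groups taken from the labels. The deposited table has 2233 small RNA identifiers. Its count columns, per the file headers, hold whole-number read counts with no normalization by the authors, and the unit was recorded as other because 11323 of 22330 count cells (50.7%) hold a missing mark in place of a number. The smallest count is 1 and no cell is 0, so missing cells were read as 0. The TPM columns deposited beside them hold each count as counts-per-million of 1 library total, with no length term. The 8 TPM columns that could be assigned to a library were used only to check library totals. The 2 TPM columns of the Lv3NC libraries were left out, since both carry the name of replicate 1 in the header. The aligner, the miRNA database and the genome build are not given in the sources used here.

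The identifiers comprise 353 miR and 16 let-7 names with the goat prefix (369 known miRNAs), 1034 predicted miRNAs, 823 RF identifiers, 4 predicted siRNAs and 3 rows for reads on intergenic, intron and exon regions. The region rows hold 44.7% to 79.0% of the reads. miRNA reads (known and predicted) numbered 3108495 to 8739602 per library, so that 1 CPM stood for 3.42 to 9.95 reads. Between 456 and 924 of the 1403 miRNAs had a count in a library.

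Counts were scaled to CPM of the miRNA reads with TMM factors (trimmed by 30% on ratios and 5% on levels), which lay between 0.828 and 1.18. miRNAs with at least 5 CPM in at least 2 of the 10 libraries were tested, 448 in all. limma 3.58.1 with statmod 1.5.0 in R 4.3.3 was fitted to log2(CPM + 1) with the mean of each of the 5 groups, an abundance trend and robust moderation, in 1 fit of all 10 libraries with 5 residual degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the miRNAs of a comparison, and the threshold was an adjusted p of 0.05. The comparisons were OV55666 against Lv5NC, KD553 against Lv3NC, each control virus against Blank, and the difference between the overexpression and knockdown effects. These comparisons, the filter, the miRNA lists and the rule for named miRNAs were chosen before the data were examined. The plan named a count model for count tables, and this departs from it: edgeR and DESeq2 were not run, because the columns with their missing marks were not taken as a plain count table, and the limma fit planned for values on a log scale was used with TMM-scaled CPM.

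Named miRNAs are, for overexpression and for knockdown, up to 10 in each direction with the largest fold change past the threshold, filled to 20 with those of smallest p at a mean of at least 50 CPM over the 4 libraries compared, together with the tested miR-200 members and the 5 most abundant miRNAs. For each virus control they are those past the threshold, filled to 5 in the same way, and for the difference the 10 with the smallest p. Values that did not pass are given as values. Lists of miRNAs (17, of which 14 had at least 3 tested members) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The lists were the let-7, miR-30, miR-15/16, miR-29, miR-34 with miR-449 and miR-221 with miR-222 families, the miR-17-92, miR-23/27/24 and DLK1-DIO3 clusters, milk fat and lactation miRNAs, innate-response miRNAs, and markers of stromal, striated muscle and blood cells. The miR-200 family (2 tested members), the endothelial marker (1) and the miR-183/96/182 cluster (0) were too small to test. Some miRNAs belong to several lists.

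Ratios of pooled reads were scaled by the TMM-adjusted miRNA reads of the libraries. They carry 95% exact intervals, which cover counting error only, since reads are not independent molecules. The relation of the first principal component to the RF share was tested with 100000 permutations. The fit was tested on simulated data of 448 miRNAs with the spread of these libraries, in 10 simulations with 50 changed miRNAs per fold. It recovered 7.8% of 2-fold, 38.6% of 4-fold, 78% of 16-fold and 86% of 64-fold changes, with 3.8 false calls per simulation. In each simulation 200 of the 448 miRNAs were changed, which makes the adjusted threshold easier to pass than with few changes. Recovery where 0 or 1 miRNA passes, as in the comparisons here, would be lower and was not simulated. The simulated miRNAs varied independently of each other. Recovery and false calls with a factor shared by the miRNAs of a library were not simulated. The median SE of a log2 fold change was 0.81.

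Alternatives planned and run were a pseudocount of 5, no filter, a filter at 50 CPM, median-of-ratios scaling, the authors' scaling to all reads in the table, a replicate block, known miRNAs only, only the groups compared, and leaving out each library. Alternatives added after the data were seen were voom weights, near-identical miRNAs summed, the reads beyond the listed identifiers given to miR-328-3p and miR-27b-3p, the miRNA total without TMM, the RF share as a covariate, and list tests with a library left out or with the known miRNAs alone as the background, and a replicate block with the KD553 numbers exchanged. Where a group was left with 1 library, that library was assumed to vary like the other groups. Scaling moved the median log2 fold change of all tested miRNAs. It was -0.08 with TMM, -0.18 with median-of-ratios, 0.03 with the authors' scaling and -0.26 with the miRNA total for overexpression, and -0.18, -0.25, -0.43 and -0.17 for knockdown. In the same order it was 0.13, 0.29, -0.26 and 0.19 for Lv5NC and -0.17, -0.05, -0.38 and -0.50 for Lv3NC against Blank.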

Results

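Small RNA libraries were made from goat mammary gland cells in which the long noncoding RNA lncRNA55666 was raised or lowered with lentivirus, and the abundance of mature miRNAs was compared between the conditions. The labels give 5 groups of 2 libraries: untreated cells (Blank), the control virus for overexpression (Lv5NC), overexpression of lncRNA55666 (OV55666), the control virus for knockdown (Lv3NC) and knockdown (KD553). The question was which miRNAs follow the level of this RNA. The transcript of lncRNA55666 itself is not measured by a small RNA table, so the size of the overexpression and of the knockdown was not analysed here. The table held 25445687 and 19616447 reads for the Blank libraries, 19174206 and 20295923 for Lv5NC, 20344191 and 19912497 for OV55666, 20393919 and 19345179 for Lv3NC, and 22288511 and 24431686 for KD553. Between 16.2% and 44.6% of these reads lay on miRNAs, which left 3108495 miRNA reads in Lv5NC replicate 1 and 8739602 in Blank replicate 2 as the lowest and highest depth. Group values are given as mean ± SD over n = 2 libraries, in counts-per-million of the miRNA reads (CPM).

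The miRNA content of the cells was dominated by a few sequences. The most abundant were miR-222-3p at 157877 ± 99543 CPM (SD, n = 10), let-7b-5p at 150036 ± 38400 CPM, miR-193b-3p at 57242 ± 40878 CPM, let-7a-5p at 46273 ± 8506 CPM and miR-99b-5p at 43647 ± 11782 CPM, and these 5 held 44.3% of the miRNA reads. The miR-200 family, which marks epithelial cells, was scarce: miR-200c averaged 8.69 CPM and miR-200b 3.93 CPM over the 10 libraries. Markers of fibroblasts and smooth muscle were abundant, with miR-214-3p at 5745 CPM, miR-143-3p at 4988 CPM, miR-145-5p at 2102 CPM and miR-199a-5p at 1896 CPM. The summed stromal markers exceeded the summed miR-200 members 278-fold to 4827-fold within a library. Only miR-200c and miR-200b of this family were tested. Any reads of the family on RF identifiers, which carry no names, are not counted, so the scarcity holds for the named miRNAs only. Markers of blood cells (miR-451-5p, 490 CPM; miR-150, 118 CPM; miR-223-3p, 117 CPM) and of endothelium (miR-126-3p, 49.2 CPM) had means in between. Those of miR-150 and miR-223-3p were raised by KD553 replicate 2, at 743 and 1018 CPM, against 18.9 to 103 CPM and 8.54 to 28.4 CPM in the other 9 libraries. Of the striated muscle markers, miR-133a-3p averaged 193 CPM, miR-133b 15.5 CPM and miR-1 3.57 CPM.

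**Figure D1:**
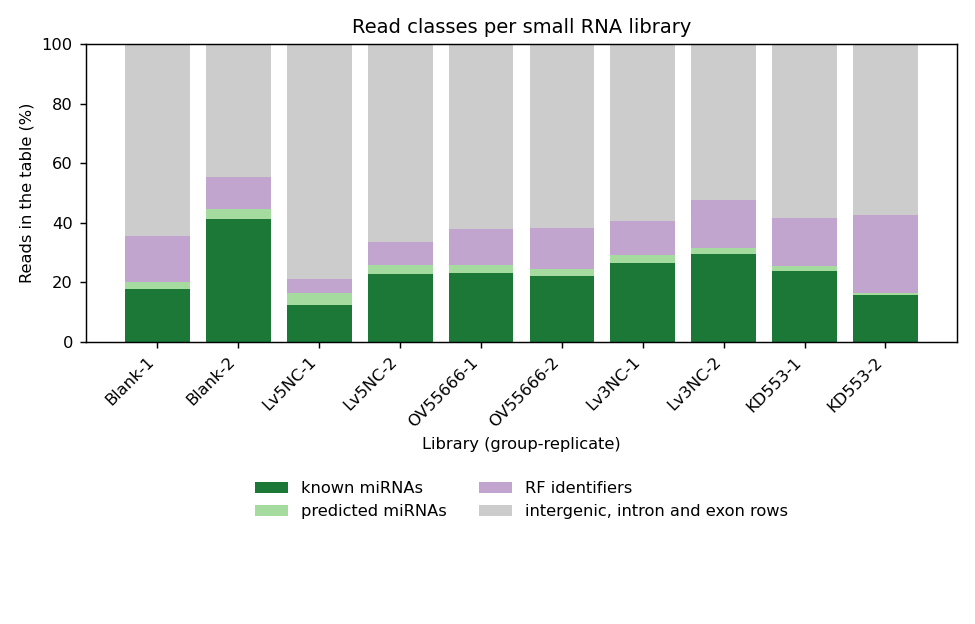
Percent of all reads in the table (vertical axis) on each class of small RNA in each of the 10 libraries (horizontal axis). Reads on the intergenic, intron and exon rows took 44.7% to 79.0% of a library, and reads on RF identifiers ranged from 4.81% in Lv5NC replicate 1 to 26.3% in KD553 replicate 2.

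Replicates were little closer to each other than libraries of different groups. They correlated at 0.907 to 0.949 (Pearson r of log2 values, 5 pairs, median 0.935), and libraries of different groups at 0.784 to 0.964 (40 pairs, median 0.925). The first principal component held 44.5% of the variance and followed the share of reads on RF identifiers, which the table lists apart from the miRNAs and does not pair with names, so that miRNA families among them were not told apart. Across the 10 libraries r was 0.882 (two-sided permutation p = 0.00061) and rho was 0.830 (permutation p = 0.00504), and this was the only such relation computed. Without KD553 replicate 2 and Lv5NC replicate 1, the libraries farthest from the median share, r was 0.679 (permutation p = 0.0648, 8 libraries), so the relation rested on them in part. These libraries also had the lowest (0.714%) and highest (3.76%) share of reads on predicted miRNAs, so the component is not tied to the RF share alone. The permutations moved libraries across groups, so they cannot separate the RF share from group differences. The RF share was 13.1 ± 3.30% in Blank, 6.27 ± 2.06% in Lv5NC, 12.8 ± 1.24% in OV55666, 13.6 ± 3.36% in Lv3NC and 21.2 ± 7.12% in KD553. With 2 libraries against 2, an exact test of a single value cannot give a p below 0.333.

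Overexpression against its control virus asked which miRNAs respond to more lncRNA55666. Of 448 miRNAs tested with limma (226 of them predicted, the others known), 1 rose and 0 fell at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 44 (16 higher and 28 lower) where 22.4 would pass by chance, and limma with voom weights called 0. The miRNA that rose was miR-328-3p, with a log2 fold change of 12.83 (SE 0.70, adjusted p = 7.12e-06). Its reads numbered 6 and 2 in the Lv5NC libraries and 54633 and 91633 in the OV55666 libraries. The pooled ratio, scaled by library size, was 16979 (95% exact interval 8617 to 39329). The same miRNA numbered 10 and 10 reads in Blank, 65497 and 25623 in Lv3NC and 38163 and 10115 in KD553. Its level was thus 1.40 ± 0.553 CPM in Blank and 0.984 ± 0.925 CPM in Lv5NC, against 14593 ± 7447 CPM in OV55666, 8994 ± 6076 CPM in Lv3NC and 5379 ± 3429 CPM in KD553. The library totals behind the deposited TPM columns of all Blank and Lv5NC libraries held 15214 to 59484 reads more than the listed small RNAs. If these were given to miR-328-3p its log2 fold change would be 1.00 (SE 0.68, adjusted p = 0.707), and the call was not kept.

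**Figure D2:**
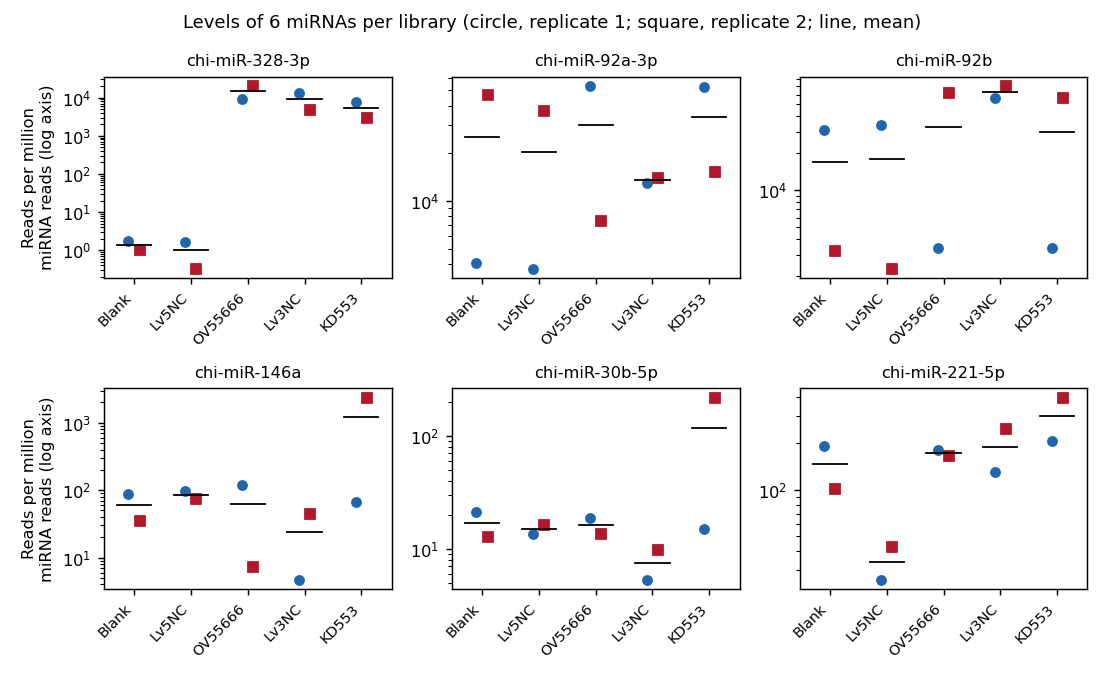
Level of 6 miRNAs in counts-per-million of the miRNA reads (vertical axis, log scale) by group (horizontal axis), with a circle for replicate 1, a square for replicate 2 and a line at the mean. miR-328-3p had at most 10 reads in each Blank and Lv5NC library and lay between 2954 and 19859 CPM in the other libraries, and miR-92a-3p and miR-92b traded places between the replicates of every group but Lv3NC.

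No other miRNA passed in this comparison, and the next smallest adjusted p was 0.324. Among miRNAs with the smallest p at a mean of at least 50 CPM, miR-221-5p, from the locus of the most abundant miRNA, stood at 34.1 ± 11.5 CPM in Lv5NC and 174 ± 11.5 CPM in OV55666 (log2 fold change 2.35, adjusted p = 0.324). It passed when adjusted over the list alone (adjusted p = 0.00718 among the miR-221 and miR-222 members), and its log2 fold change was 0.91 with the RF share as a covariate. miR-342-3p stood at 652 ± 328 and 2083 ± 232 CPM (1.77, adjusted p = 0.324). miR-30a-5p (1.55), miR-29c-5p (1.35), miR-362-5p (1.56), miR-125a-5p (1.06), let-7d-3p (1.06), miR-204-5p (1.00) and miR-342-5p (0.95) had higher values with the overexpression virus. miR-532-3p (-1.34), miR-24-3p (-2.55) and novel_mir20 (-1.55) had lower values, and the predicted novel_mir6 (1.04), novel_mir598 (1.05) and novel_mir1 (0.82) higher ones. All of these had an adjusted p between 0.324 and 0.544. Several depended on 1 Lv5NC library: without Lv5NC replicate 1 miR-30a-5p was 0.78 and miR-362-5p 0.62, and without Lv5NC replicate 2 they were 2.33 and 2.52. With the RF share as a covariate the median size of the 20 log2 fold changes named for this comparison was 1.03 in place of 1.55, among them 0.77 for miR-342-3p, 0.48 for miR-30a-5p, 0.45 for miR-362-5p, -0.56 for miR-532-3p, -1.28 for miR-24-3p and 0.40 for novel_mir598. Large fold changes with a large spread were those of miR-199b-3p (-5.54, SE 1.71), miR-199a-3p (2.66, SE 1.17), let-7e-3p (4.17, SE 1.93) and miR-27b-3p (-6.20, SE 2.89). miR-27b-3p had 2 reads in OV55666 replicate 2 and 13449 to 49845 elsewhere. The library total of OV55666 replicate 2 held 21115 reads more than the listed small RNAs. These equal 4576 CPM, within the 2967 to 8911 CPM of miR-27b-3p in the other libraries. With these reads given to it, miR-27b-3p was -0.38. It passed without OV55666 replicate 1 (-11.79) and was -0.60 without OV55666 replicate 2. miR-199a-3p and let-7e-3p passed without Lv5NC replicate 2 (4.79 and 7.99) and were 0.54 and 0.37 without Lv5NC replicate 1. With near-identical miRNAs summed, miR-199a-3p was -0.12. These omissions gave 2 and 3 calls in place of 1. miR-199b-3p was -7.58 without OV55666 replicate 1 and -3.54 without OV55666 replicate 2. Of the 20 miRNAs named here, 15 were higher and 5 lower, and 18 had both libraries of one group above both of the other, which chance gives for 33.3% of miRNAs not chosen by their p. The abundant miR-222-3p (0.65), let-7b-5p (0.21), miR-193b-3p (-0.06), let-7a-5p (0.14) and miR-99b-5p (0.38) and the epithelial miR-200c (-0.05) and miR-200b (0.94) had adjusted p of 0.801 or more.

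Of 17 miRNA lists fixed before the data were examined, 14 had at least 3 tested members. All their members are known miRNAs, and camera compares a list with all other tested miRNAs, among which the predicted ones moved apart from the known ones: for overexpression 132 known miRNAs were higher and 90 lower, and 75 predicted ones higher and 151 lower. For overexpression, camera with a preset correlation called 2 lists. In the let-7 family, whose members mark differentiated cells, 14 of 16 members were higher (median log2 fold change 0.44, adjusted p = 0.0420; 0.694 with a correlation estimated from the data). All 3 members of the miR-221 and miR-222 list, which are studied in proliferation, were higher (median 0.65, adjusted p = 0.0420; 0.694 with an estimated correlation). Against the known miRNAs alone the adjusted p were 0.135 and 0.116, and neither list passed. In Lv5NC against Blank, which uses the same Lv5NC libraries, both lists had lower values (medians -0.38 and -0.89). The summed level of let-7 was 227196 ± 11549 CPM in Blank, 185820 ± 5995 CPM in Lv5NC and 217764 ± 16921 CPM in OV55666, so the mean of OV55666 did not exceed that of Blank. For miR-221 with miR-222 it was 113049 ± 21915, 64822 ± 31491 and 127983 ± 119182 CPM, with the OV55666 libraries on both sides of Blank. A rise in OV55666 over the virus background and low values in Lv5NC alone thus cannot be told apart for these lists. fry called 0 lists, with a smallest adjusted p of 0.346. Without Lv5NC replicate 1, or without OV55666 replicate 2, camera called 0 lists. The medians of the other lists were 0.78 for miR-29, 0.59 for the imprinted DLK1-DIO3 cluster, 0.38 for miR-34 with miR-449, 0.34 for miR-30, 0.31 for miR-15/16 and -0.54 for miR-23/27/24, with adjusted p from 0.183 to 0.489. The median was 0.17 for the milk fat and lactation list, whose mean was -0.20, 0.13 for miR-17-92, 0.12 for stromal markers, whose mean was -0.01, and 0.13 for striated muscle markers. These 4 medians were negative when scaled to the miRNA total without TMM. The milk fat mean includes miR-27b-3p at -6.20, a value that rests on its 2 reads in OV55666 replicate 2. The innate-response (-0.62) and blood and immune (-0.15, mean 0.06) lists had negative medians while camera gave them an upward direction. These 6 lists had adjusted p of 0.645 or more.

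Knockdown against its control virus asked which miRNAs respond to less lncRNA55666. limma called 0 of the 448 miRNAs, with 36 at an unadjusted p under 0.05 (20 higher and 16 lower), and limma with voom weights also called 0. The smallest adjusted p, 0.171, belonged to novel_mir604, with 118 and 173 reads in Lv3NC and 0 in both KD553 libraries. It lies outside the rule for miRNAs named in this comparison and was chosen here after its values were seen. The 20 miRNAs with the smallest p at a mean of at least 50 CPM over the 4 libraries compared had adjusted p of 0.525 or 0.527. For some of them KD553 alone carried that mean, so the selection favoured higher values in KD553: miR-340-5p stood at 2.40 CPM in Lv3NC and 108 CPM in KD553, and miR-146b-5p at 1.73 and 102 CPM. miR-671-5p stood at 17.6 ± 3.64 CPM in Lv3NC and 84.4 ± 9.14 CPM in KD553 (log2 fold change 2.21), and miR-29a-3p, a regulator of collagen genes, at 2514 ± 1077 and 6914 ± 1484 CPM (1.51). miR-103-3p, studied in goat milk fat synthesis, stood at 126 ± 14.8 and 462 ± 208 CPM (1.79). miR-193b-3p stood at 121636 ± 60350 and 49269 ± 143 CPM (-1.21). Its level was 26804 CPM in Blank, 44096 CPM in Lv5NC and 44405 CPM in OV55666, so Lv3NC was the group apart. Low values in Lv3NC also entered miR-103-3p (314 CPM in Blank) and miR-27b-5p (95.9 CPM in Blank, 31.0 in Lv3NC, 117 in KD553). Not all of the 20 had this pattern: novel_mir19 stood at 208 CPM in Blank, 162 in Lv3NC and 72.2 in KD553. miR-140-5p (2.75), miR-26b-5p (2.14), miR-27b-5p (2.21), miR-17-5p (1.52), miR-29b-3p (2.09), miR-30b-5p (2.85), miR-19b-3p (2.75), miR-340-5p (3.64), miR-146b-5p (3.73), miR-146a (4.65), miR-223-3p (3.65) and novel_mir15 (2.16) had higher values. miR-193a (-1.68), novel_mir672 (-3.53), novel_mir19 (-1.15) and novel_mir662 (-1.29) had lower values. With a library left out, miR-193a ranged from -2.60 to -0.78, novel_mir672 from -5.05 to -2.06 and novel_mir662 from -1.89 to -0.69. miR-193b-3p ranged from -1.73 to -0.75 and novel_mir19 from -1.35 to -0.99. The Lv3NC replicates differed widely for novel_mir672 (11458 ± 12721 CPM) and miR-193a (7937 ± 6354 CPM). Of these 20, 15 were higher and 5 lower, and 19 had the libraries of the groups apart.

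Many of these values came from KD553 replicate 2. miR-146a, an inhibitor of innate signalling, had 2363 CPM in KD553 replicate 2, 67.1 CPM in KD553 replicate 1, and 4.67 and 44.0 CPM in Lv3NC. miR-223-3p, a myeloid miRNA, had 1018 CPM in replicate 2 and 19.6 CPM in replicate 1. Without KD553 replicate 1 limma called 15 miRNAs (14 higher, 1 lower), 8 of them among the 20, and without KD553 replicate 2 it called 0. The median size of the 20 log2 fold changes was 2.19 with all libraries, 2.94 without KD553 replicate 1, 1.27 without KD553 replicate 2 and 1.40 with the RF share as a covariate. The abundant miR-222-3p (0.49), let-7b-5p (0.07), let-7a-5p (0.05) and miR-99b-5p (-0.71) and the epithelial miR-200c (-0.03) and miR-200b (1.06) had adjusted p of 0.656 or more.

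For knockdown, camera with a preset correlation called 5 lists against all tested miRNAs, all with higher values, and 0 against the known miRNAs alone. Of the known miRNAs 140 were higher and 82 lower (median 0.29), and of the predicted ones 52 were higher and 166 lower (median -0.74). In the milk fat and lactation list 25 of 30 members were higher (median 0.69, adjusted p = 8.43e-05; 0.308 with an estimated correlation). In miR-17-92 and its paralogs 13 of 14 were higher (0.79, adjusted p = 0.00218, 0.337 estimated), in the miR-29 family 5 of 5 (1.51, adjusted p = 0.00284, 0.308 estimated), in the miR-30 family 8 of 8 (0.97, adjusted p = 0.00306, 0.337 estimated) and among the innate-response miRNAs 3 of 3 (3.73, adjusted p = 0.0118, 0.308 estimated). Against the known miRNAs alone the adjusted p of these lists were 0.0757 for milk fat and miR-29, 0.0889 for miR-30 and 0.0899 for miR-17-92 and the innate-response miRNAs. Lv3NC against Blank uses the same Lv3NC libraries, and there the medians of these lists were negative. They were -0.52 for milk fat, -0.63 for miR-17-92, -0.39 for miR-29, -0.29 for miR-30 and -0.85 for the innate-response miRNAs. The summed level of the miR-29 list was 4252 ± 632 CPM in Blank, 2716 ± 1129 CPM in Lv3NC and 7348 ± 1711 CPM in KD553. For the miR-30 list it was 1706 ± 142, 2375 ± 352 and 3762 ± 467 CPM. These sums, held mostly by miR-29a-3p and miR-30a-5p, were thus higher in KD553 than in Blank too, a difference that was not tested. For the milk fat, miR-17-92 and innate-response lists a rise in KD553 and low values in Lv3NC cannot be told apart. fry called 0 lists (smallest adjusted p 0.167). miR-146a and miR-146b-5p each passed when adjusted over the list alone (adjusted p = 0.0462). Camera called 0 lists without KD553 replicate 2, 7 without KD553 replicate 1, 3 without Lv3NC replicate 1 and 5 without Lv3NC replicate 2. Blood and immune markers (1.81), striated muscle markers (0.64), miR-15/16 (0.62), miR-221 with miR-222 (0.52), stromal markers (0.29), miR-23/27/24 (0.22) and let-7 (0.06) had positive medians that did not pass, and DLK1-DIO3 (-0.54) and miR-34 with miR-449 (-0.59) negative ones, with adjusted p from 0.0917 to 0.437. With median-of-ratios scaling the median of let-7 was negative. Scaled to all reads in the table, as the authors did, the medians of let-7, miR-221 with miR-222, stromal markers and miR-23/27/24 were negative. With that scaling, which moves all miRNAs together, the medians of the called lists were 0.11 for milk fat, 0.20 for miR-17-92, 0.35 for miR-30, 0.94 for miR-29 and 2.46 for the innate-response miRNAs.

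Each control virus against untreated cells gave the background of infection. For Lv5NC limma called 0 miRNAs, with 34 at an unadjusted p under 0.05 (19 higher and 15 lower), voom called 0, and the smallest adjusted p was 0.373. miR-342-3p stood at 2497 ± 157 CPM in Blank and 652 ± 328 CPM in Lv5NC (-2.03, adjusted p = 0.373). miR-221-5p (147 ± 65.5 and 34.1 ± 11.5 CPM, -2.05), miR-155-5p (1155 ± 92.3 and 437 ± 227 CPM, -1.50), miR-362-5p (-1.85) and miR-199a-3p (-4.45) had an adjusted p of 0.553. Without Lv5NC replicate 1 miR-362-5p was -1.0 and miR-199a-3p -2.43, without Lv5NC replicate 2 they were -2.81 and -6.58, and with near-identical miRNAs summed miR-199a-3p was -0.39. miR-221-5p (adjusted p = 0.0166) and miR-155-5p (adjusted p = 0.0393) passed when adjusted over the list alone. miR-342-3p, miR-221-5p and miR-362-5p thus had lower values in Lv5NC than in both Blank and OV55666, and both comparisons use the same Lv5NC libraries, which also had the lowest RF share. With the RF share as a covariate these miRNAs were -1.03, -0.60 and -0.74 for Lv5NC against Blank. The share separated these groups too (15.4% and 10.7% in Blank), so composition and virus cannot be told apart. Without Lv5NC replicate 2, miR-199a-3p and let-7e-3p passed. For Lv3NC limma called 1 miRNA, again miR-328-3p, which rose by 11.71 on the log2 scale (SE 0.70, adjusted p = 1.61e-05; pooled ratio scaled by library size 6820, 95% exact interval 4416 to 11166). With the reads beyond the listed small RNAs given to miR-328-3p, this was 0.97 (SE 0.68, adjusted p = 0.843). There were 25 miRNAs at an unadjusted p under 0.05 (14 higher and 11 lower), and voom called 1. miR-193b-3p stood at 26804 ± 1360 CPM in Blank and 121636 ± 60350 CPM in Lv3NC (2.09, adjusted p = 0.174). let-7d-3p (1.30), miR-99b-3p (1.23), novel_mir11 (1.46) and miR-99a-5p (-1.38) had an adjusted p of 0.792. With a library left out, let-7d-3p ranged from 0.74 to 1.82. Without Blank replicate 1, miR-505-3p also passed, for 2 calls.

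For Lv5NC against Blank, camera with a preset correlation called 5 lists against all tested miRNAs, all with lower values, and 1 against the known miRNAs alone. Of the known miRNAs 146 were lower and 76 higher (median -0.24), and of the predicted ones 172 were higher and 54 lower (median 0.71). All 7 members of the DLK1-DIO3 cluster were lower (median -1.68, adjusted p = 0.000891; 0.388 with an estimated correlation), and this list passed against the known miRNAs alone (adjusted p = 0.0159). The others were the milk fat and lactation list (23 of 30 lower, median -0.42, adjusted p = 0.0103; 0.431 estimated), miR-221 with miR-222 (3 of 3, -0.89, 0.0103; 0.388), let-7 (12 of 16, -0.38, 0.0198; 0.388) and miR-15/16 (7 of 8, -0.64, 0.0355; 0.388). Against the known miRNAs alone their adjusted p were 0.586, 0.0921, 0.486 and 0.449 in the same order. The innate-response, stromal and striated muscle lists had positive medians and a downward camera direction. Camera called 1 list without Lv5NC replicate 1 and 2 lists without Blank replicate 1. For Lv3NC against Blank it called the milk fat and lactation list (24 of 30 lower, -0.52, adjusted p = 0.0380; 0.847 estimated; 0.307 against the known miRNAs alone). Camera called 0 lists without Blank replicate 1 or without Lv3NC replicate 1, and 3 without Lv3NC replicate 2. fry called 0 lists for either virus.

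If the effects of overexpression and knockdown were opposite, their fold changes would be correlated negatively. Across the 448 miRNAs, which are not independent replicates, r was 0.254 and rho 0.307, and 255 miRNAs (56.9%) had the same sign in both comparisons. These comparisons share no library. Over the known miRNAs r was -0.03 and rho 0.0977 (0.0250 and 0.109 without miR-328-3p), and over the 226 predicted miRNAs r was 0.286 and rho 0.302. Without Lv3NC replicate 1, r over all miRNAs was 0.0859, and without KD553 replicate 2 it was 0.151. Of the predicted miRNAs 151 were lower with overexpression (median log2 fold change -0.52) and 166 with knockdown (-0.74). The 112 lower in both were about the number that unrelated sets of these sizes would share. The difference between the effects was tested directly, and limma called 1 miRNA, miR-328-3p (13.55 on the log2 scale, SE 0.99, adjusted p = 9.50e-05), with 28 at an unadjusted p under 0.05 (14 higher and 14 lower). With voom weights 0 were called, while the difference for miR-328-3p was 14.78. The number called was 7 without KD553 replicate 1, 3 without Lv5NC replicate 2 and 2 without OV55666 replicate 1. Next were novel_mir301 (adjusted p = 0.433) and, at an adjusted p of 0.750, miR-199b-3p (-7.91), novel_mir1 (1.56), let-7d-3p (1.72), novel_mir42 (-3.68) and novel_mir452, novel_mir59, novel_mir604 and novel_mir1108. novel_mir301, novel_mir452, novel_mir59, novel_mir604 and novel_mir1108 were listed at 0 in both libraries of at least 1 group, so their fold changes depend on the pseudocount. Camera called the milk fat and lactation list for this difference (25 of 30 lower, median -0.90, adjusted p = 0.0386, with 0.589 for an estimated correlation and 0.0759 against the known miRNAs alone). The list was tested with miR-27b-3p as listed, including its 2 reads in OV55666 replicate 2.

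**Figure D3:**
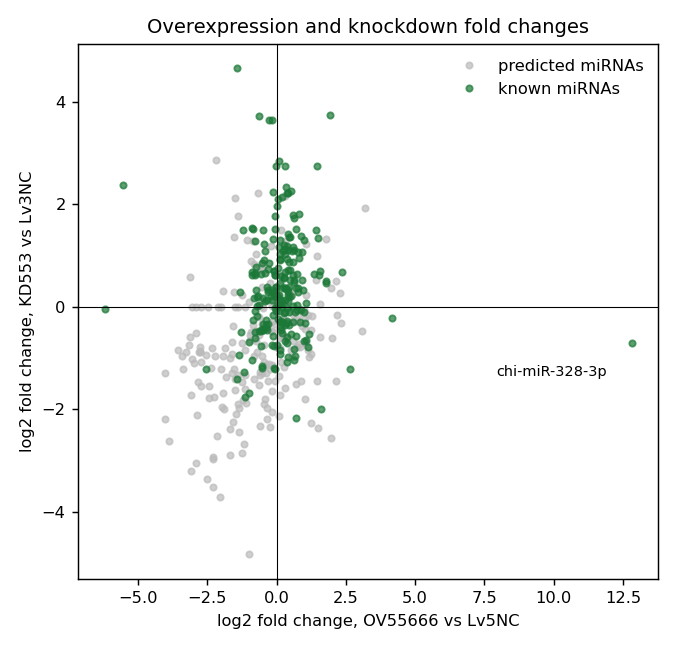
log2 fold change of knockdown against its control virus (vertical axis) plotted over that of overexpression against its control virus (horizontal axis) for the 448 tested miRNAs, one point each, with known miRNAs in green and predicted ones in grey. miR-328-3p lies apart at 12.83 on the overexpression axis, and the correlation was 0.286 over the predicted miRNAs and -0.03 over the known ones.

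RF identifiers are not paired with names in the table. Of 303 tested in the same way, limma called 0 in each of the 5 comparisons, with 28 at an unadjusted p under 0.05 for overexpression and 38 for knockdown, and smallest adjusted p of 0.378 and 0.280. Some RF identifiers, picked after their values were seen, were high only in OV55666 replicate 2 and Lv3NC replicate 1, libraries of different groups. RF00637 had 1197 and 1803 reads there and 5 to 61 elsewhere, and RF00711 had 1168 and 1606 against 24 to 188. What these libraries share was not tested, and they enter the overexpression and the knockdown comparison. The p-values in all comparisons measure only the spread between these samples, since the labels do not say whether replicates were separate cultures.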

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

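The tests of miR-328-3p, of miR-92a-3p and miR-92b, and of the RF share as a covariate were chosen only after the data were seen; the correlation over known miRNAs alone was planned as an alternative but read as a test of an explanation only after its value was seen.

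miR-328-3p stood out because its values for overexpression and for knockdown differed, by 13.55 on the log2 scale in the test of the difference itself. Most of this was the value of 12.83 for OV55666 against Lv5NC. miR-328-3p was not called for knockdown, at 8994 ± 6076 CPM in Lv3NC and 5379 ± 3429 CPM in KD553. It had 2 to 10 reads in each Blank and Lv5NC library and at least 10115 in each of the others. The control virus Lv3NC differed from Blank by 11.71 as listed (limma adjusted p = 1.61e-05). The level of lncRNA55666 alone would not give this if Lv3NC left that level unaltered. This cannot decide the question, since that level was not measured and the Blank counts may be incomplete. With the reads beyond the listed small RNAs given to miR-328-3p, Lv3NC differed from Blank by 0.97 (SE 0.68, limma adjusted p = 0.843). A candidate explanation is that reads of miR-328-3p were counted outside the identifiers analysed here. The totals implied by the TPM columns exceed the listed reads in all 4 Blank and Lv5NC libraries, by 2720 to 7178 on the CPM scale. The libraries that list miR-328-3p hold it at 2954 to 19859 CPM, so 3 of the 4 excesses lie within that range and the lowest, 2720 in Blank replicate 1, lies just below it. OV55666 replicate 1 and both KD553 libraries have an excess of at most 1 read. OV55666 replicate 2 has an excess of 21115 reads, and it is the library in which miR-27b-3p has 2 reads. The Lv3NC totals were not assessed. With the excess given to miR-328-3p the difference was 1.72 (SE 0.97, adjusted p = 0.749) in place of 13.55 (SE 0.99); the call ended because the fold shrank while its spread stayed alike. The excess does not name its small RNA, so loss from the listing and a response of miR-328-3p to the viruses other than Lv5NC cannot be told apart.

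miR-92a-3p and miR-92b, which are nearly identical, traded places between libraries. miR-92a-3p held 93.6% to 94.1% of their sum in 4 libraries and 9.92% to 21.2% in the other 6. The groups of the study do not account for it, as the replicates of 4 of the 5 groups lay on opposite sides of an equal split. Assignment of shared reads to one member or the other is a candidate explanation: the SD of the log2 sum was 0.246 of the mean SD of the members (0.440 against 1.79). For miR-199a-3p, miR-199b-3p and miR-199c-3p the same ratio was 0.170. Values of a single member of these families may thus follow the assignment of reads.

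The fold changes of overexpression and knockdown were correlated positively (r = 0.254) where opposite effects would give a negative value. Over the known miRNAs alone r was -0.0284 and rho 0.0977, and without miR-328-3p they were 0.0250 and 0.109; over the predicted miRNAs r was 0.286. This is consistent with a contribution of the predicted miRNAs to r, although the share with the same sign in both comparisons differed little, at 55.0% of known and 58.8% of predicted miRNAs. Over all miRNAs without miR-328-3p r was 0.292. With the RF share as a covariate r was 0.166, between the bounds set for and against it, with 4 residual degrees of freedom, so the contribution of library composition cannot be told apart from that of the groups. Of the 9 splits of the libraries of each comparison into pairs, 2 gave an absolute r as large, the real one included; the highest of the others was 0.266, and 9 splits are too few for a share under 0.05. An effect common to more and to less lncRNA55666 remains open and was not tested.

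The share of reads on RF identifiers, outside the miRNA comparisons, was above the control in both arms. It was 12.8% in OV55666 against 6.27% in Lv5NC, and 21.2% in KD553 against 13.6% in Lv3NC. With 2 libraries per group these differences have a smallest possible exact p of 0.333, and neither a technical nor a biological explanation was tested.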

How the results depend on the processing

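Voom weights, summed near-identical miRNAs, added excess reads, the miRNA total without TMM, the RF share as a covariate and list tests with a library left out or with a background of known miRNAs, and the exchanged KD553 numbers were chosen after the results were seen; the other alternatives were planned. The planned fits with edgeR and DESeq2 were not run.

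Of 118 counts and correlations recomputed, 91 kept their size, 26 moved and 1 reversed. Of 1126 values of named miRNAs and list counts per comparison, 1088 were unaltered in direction and call, 15 gained a call, 5 lost it, 17 moved and 1 reversed. Most named values had no call to lose, and a fold change that kept its sign counts as unaltered whatever its size. let-7e-3p for overexpression, for example, ranged from 0.37 to 7.99 with a library left out. The 1088 thus do not measure how stable the sizes were. Unless stated, the cause was not tested.

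The single call of overexpression (chi-miR-328-3p, OV55666 vs Lv5NC) went to 0 with voom weights (log2 fold change 14.07, adjusted p = 0.0826) and to 0 with the excess reads given to it (adjusted p = 0.707, the highest over its 18 alternatives; the lowest was 0 to the precision of the fit). Leaving out a library gave 1 to 3 calls. For knockdown (0) there was 1 call with a pseudocount of 5, 1 without a filter (novel_mir604 in both) and 2 with the authors' scaling, and 0 to 15 with a library left out. The 15 arose without KD553 replicate 1. For Lv5NC against Blank (0) the authors' scaling gave 1 call and leaving out a library 0 to 2. For Lv3NC against Blank (1) a pseudocount of 5, no filter and the authors' scaling each gave 2 calls, leaving out a library 1 to 2, and the excess reads 0 (adjusted p of miR-328-3p 0.843, its highest). For the difference (1) voom weights gave 0 with a larger fold change of miR-328-3p (14.78) and the excess reads 0 with a smaller one (1.72; adjusted p = 0.749, its highest), and leaving out a library 1 to 7, the 7 without KD553 replicate 1.

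The correlation of the effects (0.254) was 0.146 without a filter, 0.148 with the authors' scaling and -0.0324 with known miRNAs only, and 0.0859 to 0.287 with a library left out. The 14 list calls went to 0 with an estimated correlation and to 1 (DLK1-DIO3, Lv5NC against Blank) with the known miRNAs as the background, which leaves out the predicted ones that moved apart from them. miR-199a-3p for overexpression went from 2.66 to -0.12 when near-identical miRNAs were summed, which pools it with miR-199b-3p.

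With the replicate number as a block, the counts were 1, 0, 0, 1 and 1. The labels number the KD553 replicates in conflicting ways, and with these exchanged in the block the counts were again 1, 0, 0, 1 and 1. At an unadjusted p under 0.05 the block gave 69 miRNAs for OV55666 vs Lv5NC (44 without it, 51 with the exchange), 52 for KD553 vs Lv3NC (36 and 37), 50 for Lv5NC vs Blank (34 and 37), 34 for Lv3NC vs Blank (25 and 19) and 33 for overexpression effect minus knockdown effect (28 and 26). Deviations between replicates 1 and 2 correlated at 0.125 to 0.236 in the 6 pairs of groups without KD553 and, with the numbers of the titles, at -0.0213 with Blank, 0.0881 with Lv5NC, 0.172 with OV55666 and 0.319 with Lv3NC for KD553; the exchange would turn the signs of these 4. A factor shared by replicates of the same number is thus not excluded, and the labels name none.

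Depth limits scarce miRNAs: 1 CPM is 3.42 reads in KD553 replicate 2. The simulated fit recovered 38.6% of 4-fold changes with 200 of 448 miRNAs changed. Recovery with few changed miRNAs would be lower and was not simulated, and neither was a factor shared by the miRNAs of a library.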

Other observations

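The values here were chosen after they were seen, and no explanation of them was tested.

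KD553 replicate 2 differed from all other libraries in several miRNAs. miR-146a had 2363 CPM there and 4.67 to 119 CPM in the other 9 libraries, miR-223-3p 1018 against 8.54 to 28.4 CPM, miR-150 743 against 18.9 to 103 CPM, and miR-340-5p 209 against 2.23 to 10.7 CPM. miR-21-5p had 75647 CPM there and 11891 CPM in KD553 replicate 1. The same library had the highest share of reads on RF identifiers (26.3%) and the lowest share on predicted miRNAs (0.714%), with 456 miRNAs detected.

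The predicted miRNAs held 2.93 ± 0.760% of reads in Blank, 3.49 ± 0.389% in Lv5NC, 2.63 ± 0.365% in OV55666, 2.49 ± 0.594% in Lv3NC and 1.20 ± 0.686% in KD553 (SD, n = 2). For Lv5NC against Blank, 172 of the 226 tested predicted miRNAs had higher values (median log2 fold change 0.71).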
